A study of Mus musculus with 16 samples.

How the data were processed

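Gene expression was measured with 3' oligonucleotide arrays in liver of male KK-Ay mice, an obese strain that carries the yellow agouti allele and develops type 2 diabetes. Per the labels' protocols, total RNA was isolated from preserved liver, purified with a DNase step, and turned into biotin-labelled cRNA with a 3' in vitro transcription kit. Each of the 16 arrays held 1 mouse: 8 mice on a normal diet and 8 on the same diet with 0.1% maple syrup extract (MSE). The labels call the samples biological replicates, and no batch, scan date or hybridisation order was given in the sources used here.

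The authors deposited log2-like expression values for 45101 probe sets. The log base is inferred from their range, 5.05 to 14.6, and is not stated in the sources used here. R 3.2.2 was used upstream, per the submitters' processing notes. The summarization and normalization method was not given in the sources used here. A pair of deposited value tables was compared by the sorted values of each probe set within each diet. The largest difference was 0, so 1 set of values was analysed. Single columns were not matched. The authors' deposited table also holds a pair of false discovery rate estimates per probe set, for control below MSE and for control above MSE. These estimates exceed 1 for some probe sets, and the test behind them was not given in the sources used here.

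The spread of the deposited values is unusual and sets how they can be read. The median SD of a probe set over the 16 arrays was 4.98e-06 log2 units, 345 probe sets had an SD above 0.001 and 8 an SD above 0.1. Array medians lay between 6.0387 and 6.0388, and the lowest Pearson correlation between arrays, across probe sets, was 0.9999. Spread of this size lies far below that of ordinary array summaries, so a log2 difference here is not a fold change of the transcript. Differences are therefore given as standardized differences (the difference between group means divided by the pooled SD within groups), and as the number of the 64 pairs of 1 MSE mouse and 1 normal-diet mouse in which the MSE mouse was higher or lower. Arrays give no counts, and the number of mice limits the precision.

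Probe sets were named from the platform annotation: 34958 named 1 gene, 932 named several and were not used, and 9211 were unlisted and stay unnamed here. Of those naming 1 gene, 34754 matched a gene of the mouse reference table by gene ID, and 0 symbols changed. The probe set with the highest mean over all arrays stood for each of 18194 genes, of which 9012 had more than 1 probe set. Coordinates are not given, since no genome build was named for the annotation.

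Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a two-sided test, Benjamini-Hochberg adjustment, threshold 0.05) on the values as deposited, with no covariate. Gene lists for pathways and for liver cell types, 33 in all, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists with at least 5 measured genes. The red blood cell and adipocyte marker lists had fewer and were not tested. A list score was the mean, over the list's genes, of each gene's z value across the 16 mice. Each score was compared by an exact two-sided permutation test over all 12870 regroupings. Correlations between scores used 100000 permutations.

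The test, the lists, the alternatives and the genes to name were chosen before the data were examined. The rule named the 15 largest rises and falls among genes past the threshold. With fewer than 20 such genes it named the 10 higher and the 10 lower genes with the smallest p, by values only. Up to 4 members of each list with the smallest p were added, and for most lists those shown have an unadjusted p under 0.05. The alternatives were quantile normalization, centring on array medians, the upper part of genes by mean level, an intensity trend with robust estimation, array weights, a block for the replicate number, the mean of all probe sets of a gene, all probe sets, leaving out each mouse, camera with an estimated correlation, fry, an adjusted p threshold of 0.1, and a rank product test with regrouped samples. A rank product test with genes shuffled within arrays, with and without scaling of each probe set to a common spread, exact permutation of list scores, exact sign flips of same-numbered differences in list scores, and the acute phase score as a covariate were added after the data were seen. Scaling and rank product steps used Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.

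The steps were tested on simulated data with the spreads of these 18194 genes and 200 changed genes. In 5 runs limma recovered 2.09% of genes shifted by 1 SD, 21.5% of those shifted by 2 SD and 79.1% of those shifted by 3 SD, and 7.61% of its calls were false. Camera recovered a list shifted by 0.7 SD in 5 of 5 runs and called 0 other lists. In the measured values, however, 56 of 100 splits of the mice, the real one included, gave at least 4 called lists. The simulation therefore does not give the rate of false list calls in these data. The rank product test, run on 45101 simulated probe sets of equal spread, recovered 97.7% of probe sets raised by 3 SD.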

Results

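The series holds liver expression profiles of 16 male KK-Ay mice, 11 weeks old, 8 per diet. The diets differed in 0.1% of a maple syrup extract (MSE) and were pair-fed for 43 days, and liver was taken after 16 h without food. The comparison asks how the extract altered liver gene expression in this diabetes model. All 16 arrays had nearly the same distribution, with medians between 6.0387 and 6.0388 log2 units. Because the deposited values vary by as little as 4.98e-06 log2 units (median SD of a probe set), sizes below are in SDs within groups or in pairs of mice.

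Genes of fatty acid oxidation were higher as a set in the livers of MSE-fed mice. Of 25 measured genes, 22 were higher and 3 lower, and the list score was -0.37 ± 0.45 (SD, n = 8) on the normal diet and 0.37 ± 0.46 (SD, n = 8) on the MSE diet. The MSE mouse had the higher score in 57 of 64 pairs of mice. The shift passed camera with an adjusted p of 6.28e-11, and with an estimated inter-gene correlation the adjusted p was 5.40e-05. That correlation came to -0.022, below the preset 0.01, so the second p allowed for no more correlation between genes than the first. The score's SD within diets, 0.45 and 0.46, was more than the mean of 25 unrelated z values would give. The estimate may therefore be too low, and the second p too small. Of the list's members, 12 had an unadjusted p under 0.05, all of them higher, 8 passed when adjusted over the list alone, and 0 passed over all genes tested. Hadhb, the beta subunit of the mitochondrial trifunctional protein, was 2.15 SDs higher, in 60 of 64 pairs. Eci1, a mitochondrial enoyl-CoA isomerase, was 2.07 SDs higher, and Acaa1b, a peroxisomal thiolase, was 1.85 SDs higher. Decr1, a reductase needed for unsaturated fatty acids, was 1.74 SDs higher, in 61 of 64 pairs. The list score itself had an exact permutation p of 0.00684, or 0.212 after adjustment over the 31 lists.

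Targets of the nuclear receptor PPAR alpha outside oxidation were also higher as a set, in 17 of 20 measured genes. Their score was -0.25 ± 0.40 (SD, n = 8) on the normal diet and 0.25 ± 0.41 (SD, n = 8) on the MSE diet, higher in 53 of 64 pairs. Camera gave an adjusted p of 2.56e-04, and the call was lost at an adjusted p = 0.174 with an estimated correlation. Of the 20 genes, 6 had an unadjusted p under 0.05, 1 passed when adjusted over the list alone and 0 over all genes. Mgll, the monoglyceride lipase, was 1.87 SDs higher (59 of 64 pairs). Acot2, a mitochondrial acyl-CoA thioesterase, was 1.28 SDs higher, the hormone gene Fgf21 1.24 SDs and the pantetheinase gene Vnn1 1.19 SDs. Mgll turned direction after quantile normalization. Fgf21 varied widely for these arrays, and its means were 6.90 ± 0.02 (SD, n = 8) on the normal diet and 6.93 ± 0.03 (SD, n = 8) on the MSE diet.

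Genes of the acute phase response, mostly for plasma proteins that liver makes in inflammation, were lower as a set with MSE. Of 25 measured genes, 23 were lower, and the score was 0.32 ± 0.59 (SD, n = 8) on the normal diet and -0.32 ± 0.78 (SD, n = 8) on the MSE diet, lower in 52 of 64 pairs. Camera gave an adjusted p of 1.71e-06, and the call was lost at an adjusted p = 0.372 with an estimated correlation, where that correlation came to 0.307, and at an adjusted p = 0.0586 after quantile normalization. The exact permutation p of the score was 0.0869. Crp, C-reactive protein, was 2.20 SDs lower, in 60 of 64 pairs. Saa4, a serum amyloid A gene, was 1.16 SDs lower, the protease inhibitor gene Serpina3n 1.10 SDs, and Stat3, the transcription factor that drives the response, 1.05 SDs, although Stat3 turned direction after quantile normalization. These 4 had an unadjusted p under 0.05, Crp alone passed when adjusted over the list alone, and 0 passed over all genes. The MSE mice did not move together: replicate 7 scored 1.22 and replicate 1 scored 0.53, while the 8 normal-diet mice lay between -0.34 and 1.07 and the lowest MSE mouse was at -1.14.

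Genes of endoplasmic reticulum stress were lower in 19 of 24 members, with a camera adjusted p of 0.0167. That call was lost at an adjusted p = 0.436 with an estimated correlation, and the exact permutation p of the score was 0.203 (adjusted 0.701). It was also lost after quantile normalization (adjusted p 0.470) and when normal-diet replicate 4 or 7 or MSE replicate 2, 6 or 7 was left out (adjusted p 0.0614 to 0.166). The score was 0.20 ± 0.58 (SD, n = 8) on the normal diet and -0.20 ± 0.60 (SD, n = 8) on the MSE diet, lower in 44 of 64 pairs. The chaperone genes Canx and Pdia6 were 1.26 and 1.18 SDs lower, and both had an unadjusted p under 0.05. Sesn2 was 0.86 SDs lower and Sdf2l1 0.75 SDs lower. Here 0 genes passed when adjusted over the list alone, and 0 over all genes.

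**Figure D1:**
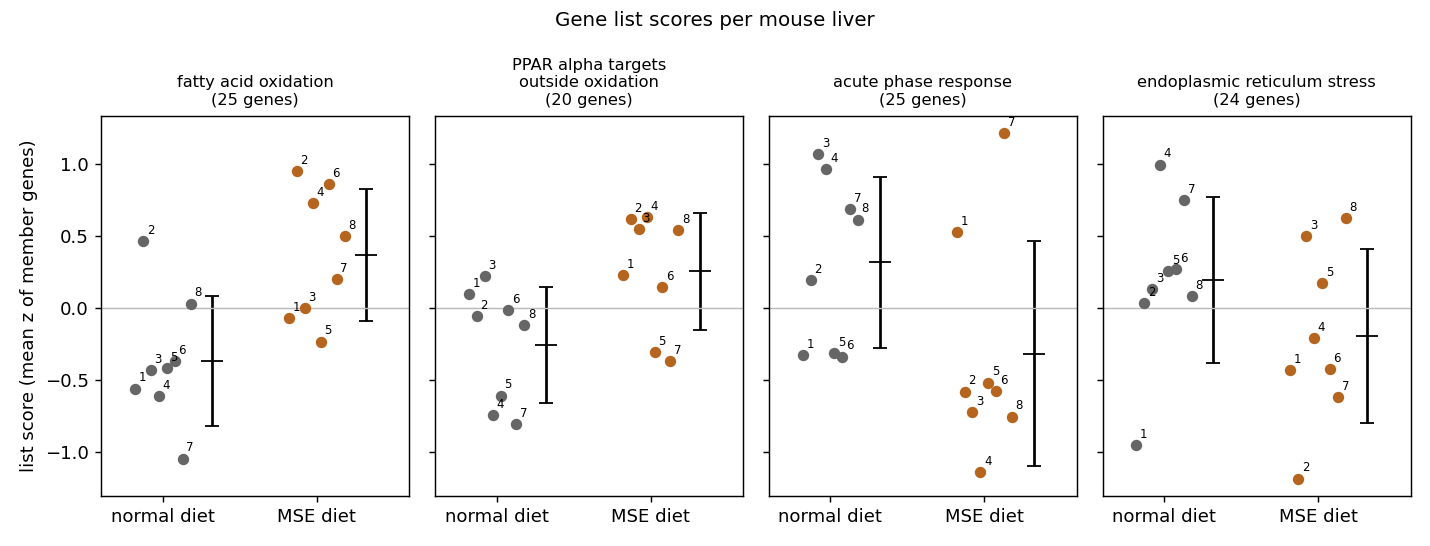
List scores (mean z of the member genes, y axis, no unit) for each mouse on the normal or the MSE diet; points are mice labelled by replicate number, and the bar beside each group is its mean and SD. The fatty acid oxidation score of the MSE mouse is higher in 57 of 64 pairs, and for the acute phase response MSE replicates 1 and 7 lie at 0.53 and 1.22.

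**Figure D2:**
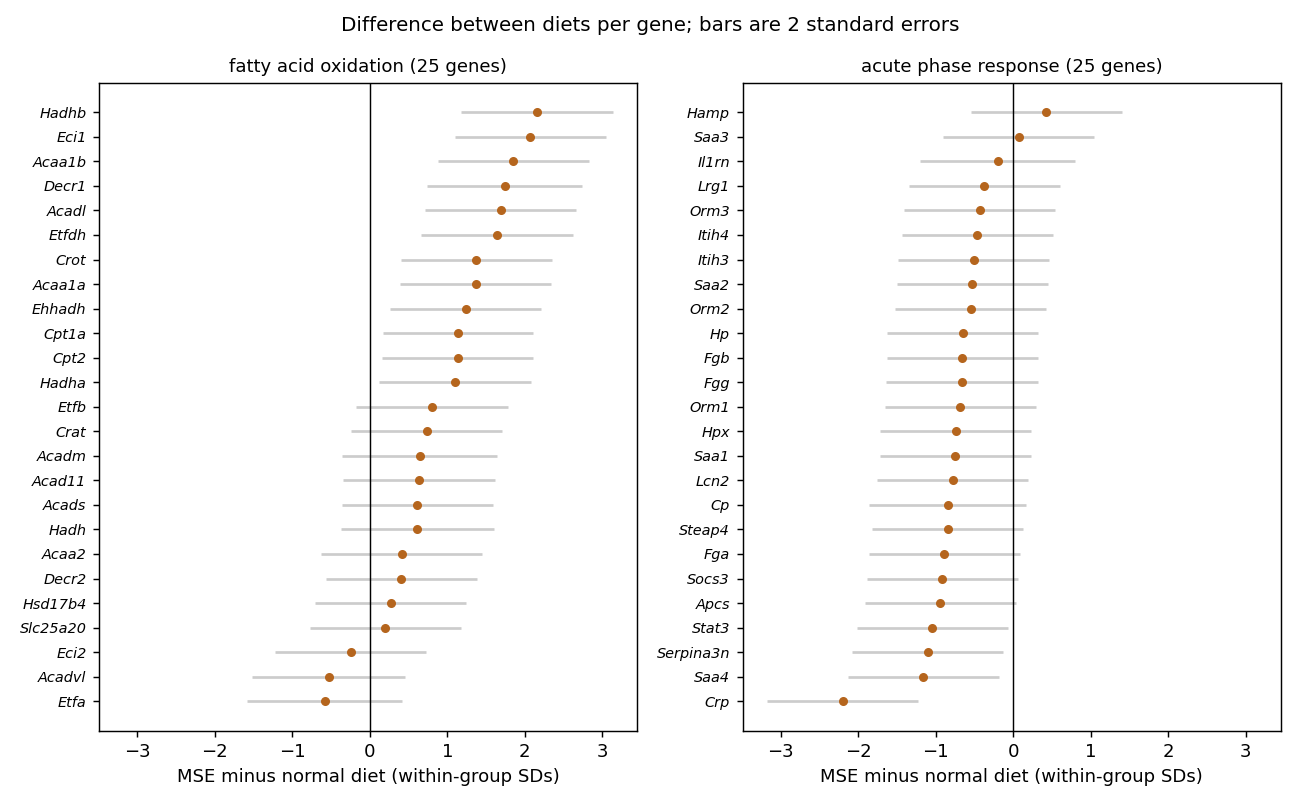
Difference between diets for each of the 25 measured genes of the fatty acid oxidation and of the acute phase list (x axis, SDs within groups, MSE minus normal diet), with bars of 2 standard errors. Of the oxidation genes 22 lie above 0, with Hadhb farthest at 2.15, and of the acute phase genes 23 lie below 0, with Crp farthest at -2.20.

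No single gene passed. Of 18194 genes, limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.0868 for Cyp2r1. At an unadjusted p under 0.05 there were 1212 genes, 471 higher and 741 lower with MSE, where chance alone gives 909.7. The rank product test with regrouped samples also gave 0 probe sets, while the rank product test with genes shuffled within arrays, added after the data were seen, gave 889 higher and 1228 lower. The genes at an unadjusted p under 0.05 and their split depended on scaling. Quantile normalization gave 1412 genes, 765 higher and 647 lower. Centring on array medians, which shifts all genes' differences alike, gave 230 genes, 157 higher and 73 lower.

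The genes with the smallest p among those lower with MSE are given by value only. Cyp2r1, a vitamin D 25-hydroxylase, was 3.40 SDs lower, in 63 of 64 pairs (limma unadjusted p 4.77e-06). Wdr7 was 3.06 SDs lower and Bet1, a SNARE of transport between the endoplasmic reticulum and Golgi, 2.87 SDs lower, each in all 64 pairs. Mrpl57, of the mitochondrial ribosome, was 2.60 SDs lower in all 64 pairs, and Tamm41, a mitochondrial enzyme of cardiolipin synthesis, 2.58 SDs. The adaptor subunit gene Ap5m1 and Ssx2ip were each 2.75 SDs lower, Selenof, a selenoprotein of the endoplasmic reticulum, 2.72 SDs, the ribonuclease P subunit gene Rpp14 2.67 SDs and the aldehyde reductase gene Akr1a1 2.62 SDs. Adjusted p values of these 10 genes ran from 0.0868 to 0.204. The direction turned for Wdr7, Mrpl57 and Ssx2ip after quantile normalization. Centring on array medians shifts the MSE minus normal difference of every gene by the same 1.31e-05 log2 units, which turned the sign of Ssx2ip, Selenof, Rpp14 and Akr1a1, whose differences are smaller than that.

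The genes with the smallest p among those higher with MSE are likewise given by value. Elovl5, an elongase of polyunsaturated fatty acids, was 2.10 SDs higher in 63 of 64 pairs, Ephx2, the soluble epoxide hydrolase, 2.27 SDs in 59 pairs, and Bdh1, a dehydrogenase of ketone bodies, 2.09 SDs in 61 pairs. Hadhb was also among the 10. Srrm2, a splicing factor, was 2.52 SDs higher in all 64 pairs, Pi16 2.28 SDs in all 64 pairs, and Ddah1, which breaks down methylarginines, 2.30 SDs in 63 pairs. Nlrc3 was 2.41 SDs higher, the exoribonuclease gene Eri1 2.25 SDs and the translation initiation factor gene Eif1ax 2.25 SDs. Adjusted p values of the 10 higher genes ran from 0.204 to 0.375, and Nlrc3 turned direction after quantile normalization. The differences of Srrm2, Nlrc3, Eri1, Eif1ax, Hadhb and Pi16 are smaller than the 1.31e-05 log2 units by which centring raises every gene's difference. That of Decr1 is too. A common rise cannot turn a higher gene, so their kept direction after centring says nothing for them.

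Of 25 genes of fatty acid and triglyceride synthesis, 15 were higher, with a camera adjusted p of 0.0977, so the set was not called. It passed when normal-diet replicate 2 or 8 or MSE replicate 3 or 7 was left out (adjusted p 0.0307, 0.0106, 0.00906 and 0.0497), in the upper part of genes by mean level (0.0299) and with the mean of probe sets (0.0446). The members with an unadjusted p under 0.05 were all higher: Elovl5, Elovl6 (1.45 SDs), and the desaturase genes Fads1 (1.25 SDs) and Fads2 (1.07 SDs). Of these Elovl5 passed when adjusted over the list alone. Of 17 lipid droplet genes 10 were higher (adjusted p 0.422), and G0s2, an inhibitor of adipose triglyceride lipase, was 1.92 SDs higher in 62 of 64 pairs and passed when adjusted over the list alone. Fitm2 was 1.07 SDs higher and Mogat1, a monoacylglycerol acyltransferase, 1.07 SDs lower. Cholesterol synthesis was higher in 11 of 20 genes (adjusted p 0.847), with Nsdhl lower in 57 of 64 pairs, Sc5d 1.10 SDs higher and Tm7sf2 1.05 SDs higher as deposited, all 3 of which turned direction after quantile normalization. The respiration and TCA cycle list was higher in 11 of 27 genes (adjusted p 0.847), with Sdhd 1.42 SDs higher and Idh3a 1.06 SDs lower as deposited and both the other way after quantile normalization.

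Other liver functions gave no called list on the values as deposited. After centring on array medians, a common shift, camera called gluconeogenesis (adjusted p 1.76e-08), xenobiotic P450 (1.53e-07), antioxidant (1.08e-10) and bile acid genes (0.0185). Over all 31 lists camera then called 13, 10 lower and 3 higher. Centring adds the same 1.31e-05 log2 units to every gene's difference, so calls made only after it cannot be told from that shift. Bile acid genes went both ways (10 of 19 higher, adjusted p 0.852): the uptake transporter gene Slc10a1 was 1.83 SDs higher and passed when adjusted over the list alone, and Cyp27a1 was 1.55 SDs lower. Nr1h4, the bile acid receptor, was 1.34 SDs lower and the export pump gene Abcc2 1.33 SDs lower as deposited, and quantile normalization turned both. In glucose metabolism, the gluconeogenesis list had 10 of 14 genes lower (adjusted p 0.439), with Fbp1 1.06 SDs higher and Tat 1.05 SDs lower, and the glycolysis list had 6 of 13 lower (adjusted p 0.927). Pgk1 was 1.70 SDs lower and passed when adjusted over the glycolysis list alone. Amino acid catabolism had 16 of 29 genes lower (adjusted p 0.927), with Glud1 1.77 SDs lower. The differences of Pgk1 and Glud1 are smaller than the common shift of 1.31e-05 log2 units that centring on array medians adds to every gene, so their sign depends on it. The xenobiotic P450 list split 8 and 8 (adjusted p 0.439), with Cyp2b10 1.29 SDs lower in 54 of 64 pairs. Antioxidant genes were lower in 18 of 27 (adjusted p 0.134, or 0.0172 without normal-diet replicate 2 and 0.0399 without MSE replicate 2), with the microsomal epoxide hydrolase gene Ephx1 1.39 SDs lower and Ugdh 1.37 SDs lower; Ugdh turned direction after quantile normalization. Female-biased liver genes (adjusted p 0.487) included Cyp2b9, 1.37 SDs lower in 57 of 64 pairs, and male-biased genes were at an adjusted p of 0.518.

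Immune and growth lists were not called on the values as deposited either, and after centring camera called cytokines and chemokines (adjusted p 0.00685), clock genes (1.22e-09) and immediate early genes (5.52e-04). Those calls after centring cannot be told from the common shift either. Inflammatory cytokines and chemokines were lower in 22 of 33 genes (adjusted p 0.320), with Il18 1.25 SDs lower as deposited and higher after quantile normalization. The interferon list was higher in 14 of 23 (adjusted p 0.774), although Bst2 was 1.69 SDs lower in 60 of 64 pairs as deposited, the other way after quantile normalization. The cell cycle list was lower in 11 of 19 genes (adjusted p 0.289), with Ccnb2 1.16 SDs lower and Ccne2 1.07 SDs lower. Matrix genes were at an adjusted p of 0.338, clock genes at 0.422, and immediate early genes at 0.847.

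Marker lists of other cell types in liver were not called on the values as deposited with the planned test and all 16 mice. Macrophage and Kupffer cell markers were lower in 15 of 18 genes (adjusted p 0.134) and neutrophil markers in 8 of 9 (adjusted p 0.134), beside the lower acute phase list. The macrophage list passed as lower when normal-diet replicate 4 or 6 or MSE replicate 1, 6 or 7 was left out (adjusted p 0.0119 to 0.0477). Stellate cell markers were higher in 9 of 9 (adjusted p 0.134, or 0.0474 without normal-diet replicate 1 and 0.0328 without MSE replicate 5). Sinusoidal endothelial markers were higher in 9 of 12 genes (adjusted p 0.0794) and passed when normal-diet replicate 2 or 8 or MSE replicate 4 or 5 was left out (adjusted p 0.0228 to 0.0485), in the upper part of genes by mean level (0.0299), with the replicate block (0.0348) and with the mean of probe sets (0.0446). After centring on array medians camera called the macrophage (adjusted p 1.13e-06) and sinusoidal endothelial lists (0.0304), values that likewise cannot be told from the common shift. The receptor gene Kdr, 1.80 SDs higher as deposited, passed when adjusted over the list alone but turned direction after quantile normalization. T and NK cell markers were at an adjusted p of 0.201, hepatocyte markers at 0.422, exocrine pancreas markers at 0.320, bile duct markers at 0.539, and B and plasma cell markers at 0.751. Of the 72 genes named by rule 40 had more than 1 probe set, and in 31 of these all probe sets went the same way. Tspan8, a bile duct marker 1.12 SDs higher, had another probe set that was lower at an unadjusted p under 0.05.

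The authors' deposited table gives a false discovery rate under 0.05 to 893 probe sets for higher and 1235 for lower expression with MSE, 157 of them in both directions. In the authors' deposited table, Elovl5, G0s2, Fgf21 and Vnn1 have a rate of 0 for higher expression, and Cyp2r1, Saa4, Serpina3n and Stat3 a rate of 0 for lower expression. Hadhb, with a rate of 0.162 in the authors' deposited table, does not pass there.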

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

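The tests of the mouse splits for the rank product calls, of the exact permutation p, and of the respiration list were chosen after the results they bear on were seen. The other tests were written down before their results.

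In 12 of 206 groups of 8 values, 1 mouse stood apart by more than the 95% critical value of Dixon's test, where chance gives about 1 in 20. The ratio of its gap to the range was 0.585 for the cell cycle score and 0.562 for the B and plasma cell marker score, both high in normal-diet replicate 1, and 0.577 for the female-biased score, high in MSE replicate 4. Among normal-diet mice it was 0.575 for Ephx2 (replicate 2, high), 0.611 for Elovl5 (replicate 7, low), 0.527 for Cyp2r1 (replicate 2, low), 0.686 for Abcc2 (replicate 4, low), 0.581 for Bst2 (replicate 1, high) and 0.528 for Fcgr2b (replicate 8, low). Among MSE mice it was 0.644 for Fitm2 and 0.555 for Nkg7 (replicate 1, high in both) and 0.533 for Oit3 (replicate 8, high). Without normal-diet replicate 2, limma called Cyp2r1 lower (adjusted p 0.00483) and Ephx2 higher (adjusted p 0.0152), and without MSE replicate 7 it called Cyp2r1 (adjusted p 0.0355). Over all alternatives the adjusted p ran from 0.00483 to 0.417 for Cyp2r1 and from 0.0152 to 0.655 for Ephx2.

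The authors' deposited table calls 1971 probe sets, 157 of them in both directions, while limma calls 0 genes, and rates from the rank product test with genes shuffled within arrays followed the authors' rates with Spearman's rho of 0.9999 in each direction, across probe sets. Unequal spread between probe sets is a candidate explanation: the median SD percentile of the authors' called probe sets was 98.1 for higher and 97.7 for lower, and none of the lower 50% by SD were called. In 100 splits of the 16 mice, the real one included, 9 gave as many rank product calls as the diets (2117 with both directions added up, highest other split 2403), and simulated values with no change but the real spreads gave 1903 to 1926 calls. After each probe set was scaled to its SD within groups, 174 calls were left, and 15 of the 100 splits, the real one included, gave as many (highest other split 431). A diet effect within these calls stays open, since the test does not tell it from spread.

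The higher fatty acid oxidation list was weighed against chance, the level of its genes, mitochondrial transcripts as a whole, and the acute phase response. Its mean t of 1.84 lay at percentile 100 of 10000 random lists matched on mean level (highest 1.26), which argues against level as the whole cause. The respiration list had a mean t of -0.143 against a standard error of 0.248, below the level set beforehand for mitochondrial transcripts as the cause. Over mice, its score differed by -0.090 (95% interval -0.718 to 0.537), and the oxidation score by 0.736 (95% interval 0.251 to 1.22). These intervals overlap and the scores were not compared with each other, so mitochondrial transcripts as a whole are not excluded. With the acute phase score of each mouse as a covariate the oxidation list kept a camera adjusted p of 1.84e-07 (mean t 1.43). That p rests on the preset correlation, at which a regrouping of the mice gave a list p of 1.58e-20. It therefore does not by itself exclude the acute phase response. For chance the tests differ: 5 of 100 splits, the real one included, gave a list with as small a camera p at the preset correlation (2.03e-12, smallest other 1.58e-20), 2 of 100, the real one included, did so with estimated correlations (1.74e-06, smallest other 2.96e-07), and the exact permutation p adjusted over the lists was 0.212. The share of splits was under 0.05 in the test with estimated correlations alone, which is 1 of several, and all of these regroup mice without regard to replicate number, so chance stays open. A diet effect on these genes is a hypothesis that these mice may carry but do not settle.

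The lower acute phase list was weighed against chance and against fewer immune cells. The exact permutation p of its score, adjusted over the lists, was 0.665, so chance was not excluded. The highest correlation of its score with the macrophage or neutrophil marker score within a diet was 0.648, and within the normal diet the macrophage score gave -0.017, so with 8 mice per diet fewer immune cells and lower hepatocyte expression cannot be told apart.

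The counts over all genes and lists were set against 100 splits of the mice, the real one included. For the 0 genes at an adjusted p under 0.05 this says nothing, since all 100 splits must give at least 0 (highest other 2). Of the 100 splits, 17 gave at least 1212 genes at an unadjusted p under 0.05 (highest other 2171), and 56 gave at least 4 called lists (highest other 12). Chance is not excluded for the last 2 counts.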

How the results depend on the processing

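The rank product tests with shuffled genes, the exact permutation and sign flips of list scores and the acute phase covariate were chosen after the data were seen. The count of genes at an adjusted p under 0.05 stayed at 0 under quantile normalization, centring on array medians, a robust intensity trend, array weights, the mean of probe sets, all probe sets, and rank products with regrouped samples. It was 1, Cyp2r1, a lower gene, among the 9097 genes in the upper part by mean level (fewer genes tested, 795 at an unadjusted p under 0.05) and 1 at an adjusted p under 0.1. With 1 mouse left out it ranged from 0 to 2 (higher 0 to 1, lower 0 to 1), the 2 without normal-diet replicate 2, and the count at an unadjusted p under 0.05 from 1020 to 1394. Rank products with genes shuffled within arrays gave 2117 calls on 1962 probe sets, and 174 calls after scaling each to the same spread. Centring on array medians left 230 genes at an unadjusted p under 0.05: array medians differ by 1.39e-04, and the median SD of a gene went from 5.63e-06 to 3.10e-05. After quantile normalization it was 4.46e-05, 1466 genes took the same value on all arrays, and 17 of the 72 named genes had no difference left.

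The 4 called lists became 2 under quantile normalization, 13 under centring (3 higher and 10 lower), 1 with an estimated correlation, 0 with fry, 1 with the acute phase covariate and 0 with exact permutation of scores, and ranged from 3 to 7 with 1 mouse left out (7 without normal-diet replicate 2). The fatty acid oxidation list had adjusted p values of 1.13e-13 to 3.10e-08 with 1 mouse left out, 0.126 with fry and 0.212 with exact permutation. For PPAR alpha targets these were 1.70e-05 to 0.00347, 0.364 and 0.434, with 0.174 for an estimated correlation and 0.0571 with the covariate. For the acute phase list they were 4.19e-12 to 3.56e-04, 0.639 and 0.665, with 0.372 for an estimated correlation and 0.0586 after quantile normalization. For endoplasmic reticulum stress they were 1.47e-04 to 0.166, 0.653 and 0.701, with 0.436 for an estimated correlation, 0.470 after quantile normalization and 0.0571 with the covariate. Lists not called by the planned test passed under an alternative 31 times, among them sinusoidal endothelium 8 times (0.0348 with the replicate block), fatty acid synthesis 6 and macrophage markers 6 (1.13e-06 after centring). Fry and exact permutation test a list by itself, not against other genes, and the cause of the other losses was not tested. The list kept with an estimated correlation is the oxidation list, whose estimate may be too low, so that call says little.

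Of 1628 comparisons of a named gene with an alternative, 31 reversed, 22 under quantile normalization and 9 under centring. The 9 follow from its construction, since it shifts every gene's difference by the same 1.31e-05, and say nothing about those genes in particular. After quantile normalization the MSE minus normal difference (log2) was -3.46e-07 for Nlrc3, 1.71e-05 for Wdr7, 7.17e-05 for Ssx2ip, 1.77e-05 for Mrpl57, -7.68e-04 for Mgll, 5.46e-06 for Nsdhl, -1.75e-05 for Sc5d, -8.21e-05 for Tm7sf2, 1.56e-04 for Nr1h4, 7.85e-06 for Abcc2, 9.98e-05 for Ugdh, 1.61e-04 for Il18, 1.88e-04 for Stat3, 6.33e-05 for Bst2, 2.07e-04 for Pcna, 7.14e-05 for Btg2, -1.82e-04 for Sdhd, 2.27e-05 for Idh3a, -3.27e-07 for Nkg7, -1.45e-04 for Kdr, -1.12e-05 for Fcgr2b and 2.20e-04 for Stab2. After centring it was 1.05e-06 for Ssx2ip, 5.36e-06 for Selenof, 5.86e-06 for Rpp14, 6.48e-06 for Akr1a1, 8.76e-06 for Nsdhl, 6.83e-06 for Pgk1, 3.85e-06 for Glud1, 4.03e-06 for Pcna and 8.87e-06 for Sult3a1.

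With the replicate number as a block, limma called 1 gene, lower with MSE (Wdr7, adjusted p 0.0435), 1614 genes at an unadjusted p under 0.05 and 5 lists. Same-numbered mice of both diets had correlations of their deviations between -0.026 and 0.218. Only 5 of 8 were over 0.1, so the numbers were not taken as pairs. Yet 4 of 8 normal-diet mice correlated best with their own number. The mean correlation was 0.129 for the same number and -0.018 for different numbers (one-sided permutation p 9.90e-04). Both are a hint from the data of something shared by number, for which the main tests do not allow. Column headers of the other deposited table number the samples with gaps that differ between the diets. A shared replicate number may therefore not mean a shared number there. In exact two-sided sign flips of same-numbered differences the oxidation and the PPAR alpha scores were each higher with MSE in 8 of 8 (exact p 0.00781, the smallest that 256 flips can give; adjusted 0.121). The acute phase and endoplasmic reticulum stress lists had an adjusted p of 0.554 there. That 0 lists passed says little, since over 31 lists the smallest p passes only where at least 5 lists reach it. The other deposited table held the same values and gave no alternative.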

Other observations

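The lists and correlations in this part were chosen after the results were seen, and after adjustment over the 15 added lists no exact permutation p of a score passed. Genes of the secretory path between the endoplasmic reticulum and Golgi were lower as a set with MSE. Of 34 genes listed for COPI and COPII coats and their cargo receptors, the SNARE genes Bet1 and Sec22b among them, 30 were lower. Camera gave an adjusted p of 3.80e-05 over the 15 added lists, and 0.00119 with an estimated correlation. That correlation came to 0.003, below the preset 0.01. The score varied within diets more than the mean of 34 unrelated z values would, so the estimate may be too low. The exact permutation p of the score was 0.0701 (adjusted 0.263). The score was 0.24 ± 0.55 (SD, n = 8) on the normal diet and -0.24 ± 0.41 (SD, n = 8) on the MSE diet, lower in 51 of 64 pairs. Bet1 prompted the list and is in it, so it is not independent of that gene. Cope was 1.45 SDs lower, Sec22b 1.34 SDs and Surf4 1.33 SDs.

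Cytosolic ribosomal protein genes were higher in 37 of 46, with a camera adjusted p of 3.80e-05, 7.06e-04 with an estimated correlation, and an exact permutation p of the score of 0.0589 (adjusted 0.263). The estimated correlation came to -0.021, below the preset 0.01, so it allowed for no more correlation between genes than the preset did. The score's SD was 0.45 on the normal diet and 0.41 on the MSE diet. That is more than the mean of 46 unrelated z values would give, so the estimate may be too low. Rps20 was 1.38 SDs higher and Rps4x 1.37 SDs, while Rps27l was lower in 56 of 64 pairs. Proteasome subunit genes were higher in 28 of 39 (adjusted p 0.00769, 0.0111 with an estimated correlation of -0.016, also below the preset, exact permutation p of the score 0.431, adjusted 0.647). The proteasome score had an SD of 0.51 on the normal diet and 0.76 on the MSE diet, so that estimate may be too low as well. Mitochondrial ribosomal protein genes split into 37 higher and 36 lower (adjusted p 0.770). The higher genes of the fatty acid oxidation list were spread over its mitochondrial part (16 of 18 higher) and its peroxisomal part (6 of 7 higher), which restates that list. Peroxisome biogenesis genes were at an adjusted p of 0.746. Genes of long-chain and polyunsaturated fatty acid synthesis were higher in 14 of 20 (adjusted p 0.00769, and adjusted p = 0.0716 with an estimated correlation), but 4 of the 6 members with an unadjusted p under 0.05 are Elovl5, Elovl6, Fads1 and Fads2, already seen to be higher, so the list is not independent of them. The rest of the 6 were Elovl2 and Tecr, 1.12 and 1.31 SDs higher.

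Across the 16 mice the oxidation score correlated with the score of PPAR alpha targets (Pearson's r 0.686, permutation p 0.00347, adjusted 0.0278 over 8 relations; Spearman's rho 0.621, permutation p 0.0120). Within diets r was 0.501 on the normal diet (exact permutation p 0.215) and 0.522 on the MSE diet (exact permutation p 0.189), and both lists were higher with MSE, so the pooled r is not separate from the difference between diets. Without the 2 mice farthest from the median the pooled r was 0.522. With the acute phase score the oxidation score had r -0.485 (permutation p 0.0584, adjusted 0.117; rho -0.565, permutation p 0.0249), -0.150 within the normal diet and -0.398 within the MSE diet. With neutrophil markers the oxidation score had r -0.457 (permutation p 0.0767, adjusted 0.123; rho -0.550, permutation p 0.0296), and r -0.347 without the 2 mice farthest from the median. Within diets that r was 0.213 on the normal diet (exact permutation p 0.617) and -0.857 on the MSE diet (exact permutation p 0.0109, not adjusted), and the difference between diets was not tested.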
